A study of Mus musculus with 172 samples.

How the data were processed

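RNA was sequenced from 172 libraries of 9 tissues of mice kept for 10 weeks in 4 arms (chow or high-fat diet, water or tea). Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded kit that selects poly(A) RNA. Per the submitters' processing notes, reads were trimmed with fastp 0.23.4 and aligned to mm39 with STAR 2.7.11b. Per the file headers, the deposited counts are whole reads per gene name from featureCounts 2.0.6 on a filtered GENCODE vM34 annotation, and the filter is not stated. Per the file headers, mates of a pair were counted individually and without regard to strand. Of the counts above 0, 62.7% were even, and 77.2% of those under 20. Counting errors are therefore larger than the totals imply, and genes that overlap on opposite strands, or near-identical copies, cannot be separated well. The files hold 33880 genes, of which 30347 matched a biotype and 3533 did not. Xist stayed at or below 0.94 CPM and Ddx3y at or above 5.92 CPM in all libraries.

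Each tissue was analysed by itself in edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Genes with low counts were removed with filterByExpr at a minimum count of 10, libraries were scaled by TMM, and 1 mean per arm was fitted with the robust quasi-likelihood method. The contrasts were the diet (HW against CW), tea under the high-fat diet (HT against HW), tea under chow (CT against CW), and the difference of the tea effects between the diets (HT minus HW, less CT minus CW). P-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, with calls at 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM on TMM-scaled totals, and sums of markers and the clock and heat-shock measures use plain totals.

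Gene lists, 55 in all (14 general, 6 of markers of other cell types and 35 of single tissues), were fixed before the data were examined, as were the contrasts, the tests and the rule for naming genes. Lists with 5 or more measured genes were tested with camera on log2 CPM (prior count 2) at the preset correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over the lists and pairwise contrasts of a tissue. Members passing edgeR were counted after adjustment over all genes and over the list alone.

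The rule named up to 5 higher and 5 lower protein-coding genes per contrast with the largest changes among those passing, with a mean of 5 CPM or more in 1 arm and no overlap of the arms. It added up to 4 members of each list that was called or had 2 or more members passing, up to 10 genes called in the most tissues, and up to 5 genes per interaction. It gave 1504 entries, of which the text discusses 212. That subset was chosen after the values were seen, and Cps1 in skeletal muscle was left out because its HW libraries are all at 0. Names of transcripts of other organs serve as markers. Some genes given by the rule are not reported here. Of the 212, 169 kept their call in all alternatives and 43 lost it in at least 1.

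Alternatives set before the data were examined were RLE in place of TMM scaling, no filter on low counts, the DESeq2 1.42.0 Wald test, only the arms of the contrast in the fit, the replicate number as a block, and leaving out each library. Added after seeing the data were the fit without 17 libraries that stood apart, counts divided by 2, and the first 2 principal components as covariates. A library stood apart when its sum of acinar, muscle fibre, hepatocyte or lymphocyte markers was over 5 times the tissue's median and over 100 CPM, or when its correlation with the tissue's other libraries was low (1.5 interquartile ranges). White adipocyte and erythroid markers did not count for this rule, so the 5 HW livers, which pass its limits for adipocyte markers, stayed in. The reversal of diet and tea effects, which share the HW libraries, was set against simulated unchanged groups and against splits of the HW libraries. Mitochondrial shares of counts and heat-shock means were compared by exact permutation after the values were seen. The tea effects under the 2 diets were correlated across genes and tested by exact regrouping of libraries.

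The pipeline was tested on simulated data with 50 changed genes per fold on HW against CW. In brain (19209 genes) it recovered 18, 60, 88 and 98% at 1.5-, 2-, 4- and 8-fold, with 14 false among 146 calls. In liver (15235 genes) it recovered 30, 74, 98 and 100%, with 8 false among 159, and in bone marrow (18141 genes) 38, 90, 98 and 98%, with 7 false among 169. Unchanged data gave 0 calls in each of the 3 tissues.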

Results

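The design asks what a high-fat diet and Tibetan tea, a dark tea made by microbial fermentation, do to gene expression across mouse organs. Poly(A) RNA of 9 tissues was sequenced after 10 weeks in 4 arms. CW and CT ate chow, HW and HT a high-fat diet; CW and HW drank water, CT and HT tea. The series names 5 animals per arm, so the libraries of a group are taken as separate animals, and p-values measure the spread between them. The 172 libraries formed 36 groups, of which 31 held 5 libraries. The numbers of liver HT6 and pancreas CT7 lie beyond 5, in place of 2 in liver HT and of 3 in pancreas CT, and the labels do not say which animals they mark. Their correlations with the rest of their tissue were 0.952 and 0.941 (tissue medians 0.973 and 0.954). Pancreas had 4 libraries in CW and 4 in HT, and bone marrow had 3 in CW, 2 in CT, 5 in HW and 4 in HT. Total counts per library, in megareads (M, mates counted individually), ran from 38.7 to 136.1 M with a median of 65.0 M. Pancreas had the lowest totals, 38.7 to 50.5 M, and its 10 most abundant genes took 60.9 to 65.9% of them. The other ranges were 53.1 to 72.1 M in brown adipose tissue (BAT), 58.7 to 81.3 M in bone marrow, 54.3 to 82.9 M in brain, 56.9 to 83.9 M in colon, 53.9 to 83.1 M in heart, 64.3 to 81.7 M in kidney, 52.2 to 76.9 M in liver and 56.5 to 136.1 M in skeletal muscle. Levels below are CPM on library totals scaled by TMM (sums of marker genes on plain totals), mean ± SD over the libraries of an arm (n = 5 unless stated above), log2 fold changes are given ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mitochondrial shares of counts were compared between arms in 27 exact two-sided permutation tests. None passed adjustment (lowest adjusted p = 0.214), and a lone one cannot, even without overlap. Library HW2 is replicate 2 of HW.

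**Figure D1:**
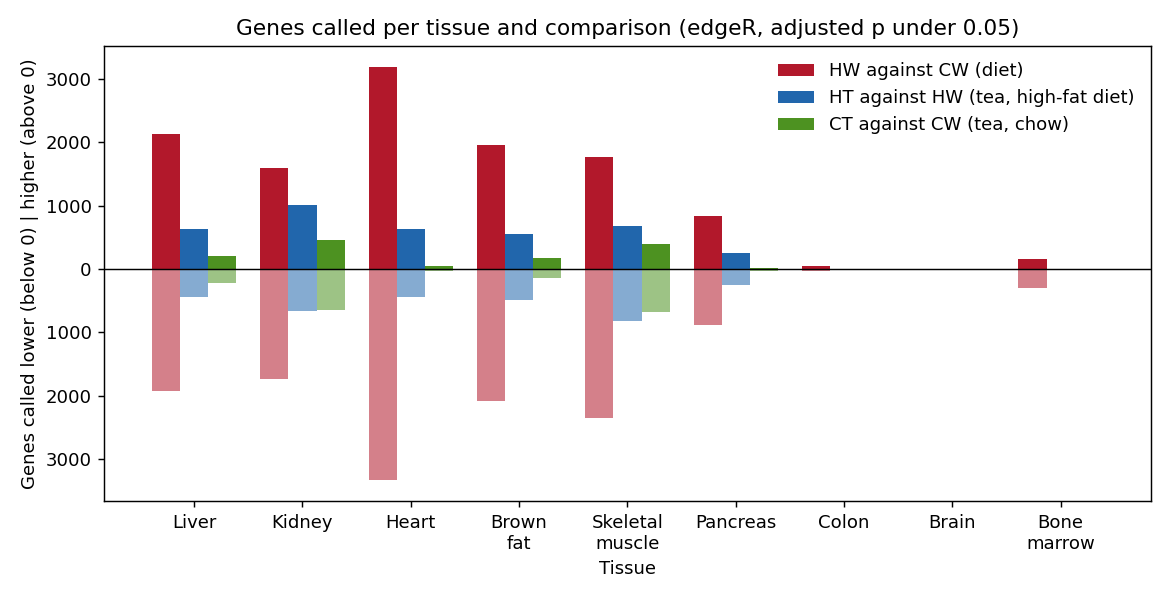
Number of genes passing edgeR's quasi-likelihood test at an adjusted p of 0.05 per tissue, higher genes above and lower genes below 0, for the diet (HW against CW), tea under the high-fat diet (HT against HW) and tea under chow (CT against CW).

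Clock genes separated the diets in nearly every organ. Dbp, a clock-controlled transcription factor (chromosome 7, 45354512 to 45359627, mm39), was higher in HW than in CW in 9 of 9 tissues, with log2 fold changes from 0.96 to 5.73. Nr1d2 and Tef, also clock-controlled, were higher in 8 tissues and Ciart, a repressor of the clock, in 7. Bmal1 and Npas2, activators of the clock, were lower in 7 tissues, with log2 fold changes from -4.10 to -2.27 for Bmal1 (chromosome 7, 112806672 to 112913333) and from -5.42 to -2.18 for Npas2. Pdk4, which restrains glucose oxidation (chromosome 6, 5483351 to 5496309), was lower in 8 tissues with log2 fold changes from -4.02 to -1.02. The sulfotransferase Sult1a1 was lower in 8 tissues, and the cell-cycle inhibitor Cdkn1a and the thioesterase Acot1 were lower in 7. Under the high-fat diet tea raised Sult1a1 in 7 tissues, with log2 fold changes from 0.84 to 1.11, and Gstt2, a glutathione transferase, in 6. Under chow tea raised Dbp and Nr1d1 in 5 tissues each. Without the 17 libraries that stood apart by markers or correlation, Dbp passed in 4 and Nr1d1 in 3: skeletal muscle, left with 2 CW libraries, lost both (adjusted p = 0.112 and 0.288) and heart lost Nr1d1. With only CT and CW in the fit Dbp passed in 6 and Nr1d1 in 2. For the diet Dbp, Pdk4 and Cdkn1a passed in 8, 7 and 6 tissues without these libraries, and Dbp, Cdkn1a and Acot1 in 8, 6 and 6 with only HW and CW in the fit. With only HW and HT in it Sult1a1 passed in 6 and Gstt2 in 5. Acot1 has the near-identical neighbour Acot2, so that their counts are uncertain.

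The log2 ratio of Dbp to Bmal1 within each library did not overlap between HW and CW in 8 of 9 tissues. HW exceeded CW by 2.34 in brain, 8.62 in BAT, 7.27 in heart, 9.05 in kidney, 8.92 in liver, 9.22 in pancreas, 7.11 in colon and 6.58 in skeletal muscle. In bone marrow the difference was 0.75 and the arms overlapped. The mean of CT lay between CW and HW in all 9 tissues. CT exceeded CW by 1.29 in brain, 3.51 in BAT, 1.69 in heart, 4.12 in kidney, 4.72 in liver and 2.28 in pancreas with no overlap, and by 2.72 in colon, 1.26 in skeletal muscle and 0.08 in bone marrow with overlap. HT differed from HW by -0.75 to 0.60 across tissues, and the ranges of these arms overlapped except in bone marrow, where HT was 0.58 higher. The ratio was chosen after the values were seen. The labels give no hour of collection. In any gene that varies by hour, a difference in hour between arms cannot be told apart from diet or tea.

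**Figure D2:**
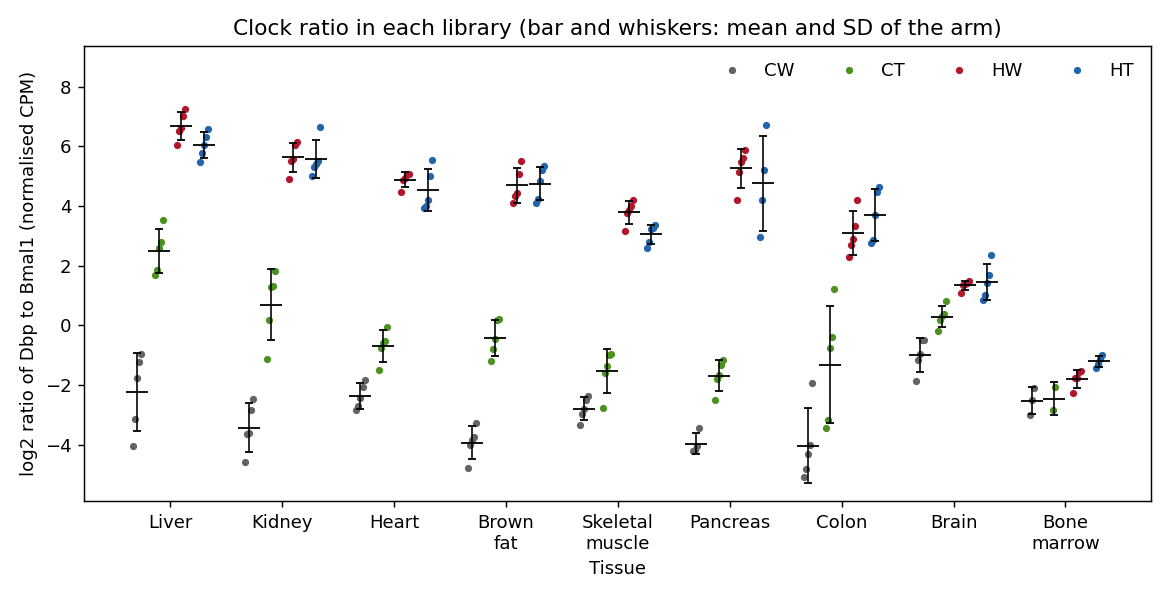
Log2 ratio of the clock genes Dbp and Bmal1 in each library (points) by tissue and arm. HW lies above CW by 0.75 (bone marrow) to 9.22 (pancreas).

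In liver, genes of sterol synthesis were higher and genes of fatty-acid oxidation lower in HW than in CW. Hour of collection was not told apart from diet for these genes. Srebf1, a transcription factor of lipid synthesis, rose from 18.7 ± 4.05 to 212 ± 40.6 CPM (log2 fold change 3.50 ± 0.24, adjusted p = 4.71e-09), and 20 of the 24 genes of the cholesterol synthesis list rose and 0 fell, among them Stard4 (2.29 ± 0.21) and Insig1 (2.12 ± 0.22). Of the 31 genes of the PPARA and fatty-acid oxidation list 0 rose and 23 fell, with Cyp4a10 at 6630 ± 852 CPM in CW and 734 ± 403 in HW, and Cpt1a, which admits long-chain fatty acids to mitochondria, at 1210 ± 61.4 and 655 ± 31.8. The bile acid enzyme Cyp8b1 fell (-2.09 ± 0.22) while Abcg5 (1.49 ± 0.14) and Abcg8 (1.68 ± 0.13), which export sterols into bile, rose. Of 26 genes of amino acid catabolism 14 fell and 3 rose, with the urea cycle enzyme Asl at -2.18 ± 0.24, and of 29 interferon response genes 23 rose and 0 fell, with Isg15 at 1.66 ± 0.22 and Psmb9 at 1.28 ± 0.17. In the clock list of 20 genes, 15 rose and 4 fell.

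By the naming rule, the largest increases in liver were of Hsd3b5, a steroid dehydrogenase of male liver (4.87 ± 0.50, adjusted p = 1.4e-06), Car3 (4.86 ± 0.76), Dbp (4.72 ± 0.33) and Cfd (5.02 ± 1.33, adjusted p = 0.00956). The largest decreases were of the leptin receptor Lepr (-5.23 ± 0.77), Cntnap1 (-4.77 ± 0.42), Cdkn1a (-4.70 ± 0.55) and the lipid droplet gene Cidec (-4.41 ± 0.56), and the insulin-repressed Igfbp1 fell (-3.54 ± 0.65). Car3 and Cfd belong to the white adipocyte markers, of which 3 of 11 rose and 2 fell, with a median of -0.03 and a mean of 0.51 (camera adjusted p = 0.94, and adjusted p = 0.992 with an estimated correlation). 21 of the sterol genes rose, 24 of the oxidation genes fell and 2 rose, 14 of amino acid catabolism fell and 4 rose, 24 of the interferon genes rose and 1 fell, and 15 of the clock genes rose and 4 fell, adjusted over the list alone. The camera test gave adjusted p = 1.96e-12, 4.78e-12, 8.74e-05, 4.21e-08 and 9.94e-05 in this order, and adjusted p = 0.455, 0.455, 0.729, 0.455 and 0.455 with an estimated correlation. In all 4050 of 15471 genes passed, 2129 higher and 1921 lower. Cyp4a10, Cyp4a14 and Cyp4a31 are near-identical neighbours, and reads may be divided between them.

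Tea under the high-fat diet moved many of these liver genes the other way. Cyp4a31 rose from 19.3 ± 4.68 to 128 ± 19.4 CPM (2.73 ± 0.17, adjusted p = 2.61e-09), Cyp4a10 (2.36 ± 0.31), Cyp4a14 (2.86 ± 0.55) and Cpt1a (0.90 ± 0.09) rose, and 8 of 31 genes of fatty-acid oxidation rose and 0 fell. Amino acid catabolism had 14 of 26 genes higher and 1 lower, with Asl at 2.04 ± 0.24 and Ass1, also of the urea cycle, at 1.56 ± 0.22. The gluconeogenic enzyme Fbp1 (1.01 ± 0.11) and Cyp8b1 (2.01 ± 0.22) rose, as did Cntnap1 (3.73 ± 0.41), Slc16a5 (2.97 ± 0.47), Eif4ebp3 (2.82 ± 0.45) and the female-biased Cux2 (3.97 ± 0.88). Gbp10 (-2.82 ± 0.33), Clec2h (-2.08 ± 0.31), Cfd (-4.68 ± 1.31, adjusted p = 0.0391) and Car3 (-2.52 ± 0.68, adjusted p = 0.0327) fell. The call on Cfd ended when any of HW1, HW4, HT1, HT3, HT4 or HT5 was left out (adjusted p 0.0643 to 0.119), and that on Car3 without any of these or HW3 or HW5 (0.0526 to 0.0723). With no filter on low counts both calls ended (0.0634 for Cfd and 0.0529 for Car3), and with only HW and HT in the fit that on Car3 did (0.0565). 17 genes of oxidation rose, and 15 of amino acid catabolism rose and 1 fell, adjusted over the list alone. Tests with camera gave adjusted p = 7.7e-11 and 1.86e-11 for these lists, and adjusted p = 0.455 for both with an estimated correlation. In all 1075 genes passed, 635 higher and 440 lower. Without HT6 1454 passed, 690 higher and 764 lower. With HT6 and only HW and HT in the fit 585 did.

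Tea under chow raised Dbp in liver from 4.03 ± 2.22 to 33.0 ± 4.06 CPM (3.04 ± 0.31, adjusted p = 4.13e-05), together with the clock gene Per3 (2.68 ± 0.32) and Ppargc1a, a coactivator of mitochondrial and gluconeogenic genes (2.06 ± 0.36). Cdkn1a (-2.70 ± 0.49) and Pdk4 (-2.62 ± 0.35) fell. Of 20 clock genes 5 rose and 2 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.00783, and adjusted p = 0.455 with an estimated correlation). In the unfolded protein response list 1 of 22 genes fell, or 10 adjusted over the list alone (adjusted p = 2.59e-05, and adjusted p = 0.501 with an estimated correlation). The 420 genes passing were 206 higher and 214 lower. Their number was 188 to 466 with 1 CW or CT library left out. Without HT6 860 genes passed, with only CT and CW in the fit 760, and in DESeq2 779. The effect of tea differed between the diets for 442 genes, 284 higher and 158 lower, for 801 without HT6 and for 740 in DESeq2. Among them was Cyp4a31, with a difference in log2 fold change of 2.28 ± 0.23 (adjusted p = 1.82e-05).

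In kidney, fatty-acid oxidation fell with the high-fat diet. In that list 29 of the 32 genes fell and 0 rose, with Pdk4 falling from 803 ± 57.0 to 74.4 ± 12.8 CPM (-3.43 ± 0.16, adjusted p = 4.89e-11), Cyp4a14 from 2290 ± 450 to 81.4 ± 71.2 (-4.81 ± 0.54) and Acot2 from 125 ± 11.5 to 28.5 ± 6.10 (-2.13 ± 0.11). Dbp (5.07 ± 0.32), Per3 (2.61 ± 0.14) and the organic solute transporter Slc51a (1.88 ± 0.20) rose. Heme oxygenase Hmox1 (-4.31 ± 0.53), Kcnip2 (-4.12 ± 0.28), Bmal1 (-4.01 ± 0.26), Npas2 (-4.21 ± 0.26), the oxidative stress gene Nqo1 (-1.30 ± 0.13) and Pck1, of gluconeogenesis (-0.52 ± 0.09), fell. Of 29 interferon response genes 18 rose and 0 fell, with Bst2 at 0.69 ± 0.10. Sterol synthesis had 12 of 24 genes higher and 1 lower, and the clock list 13 of 20 higher and 4 lower. Lymphocyte markers moved with the interferon genes: 5 of 19 rose and 0 fell.

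For the oxidation list camera gave adjusted p = 1.13e-40 and adjusted p = 0.0221 with an estimated correlation. For interferon, sterol, clock and lymphocyte genes it gave 1.52e-10, 2.87e-05, 0.000194 and 0.00253, and adjusted p = 0.44, 0.53, 0.44 and 0.612 with an estimated correlation. Adjusted over the list alone, 31 oxidation genes fell, 23 interferon genes rose, 15 sterol genes rose and 1 fell, 13 clock genes rose and 5 fell, and 7 lymphocyte markers rose. In kidney 3342 of 17953 genes passed for the diet, 1601 higher and 1741 lower.

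In kidney, tea under the high-fat diet raised 29 of the 32 oxidation genes and lowered 0. Cyp4a14 rose from 81.4 ± 71.2 to 1220 ± 725 CPM (3.90 ± 0.52, adjusted p = 0.000245), Cyp4a10 from 403 ± 126 to 1770 ± 295 (2.13 ± 0.17) and Acot1 from 59.9 ± 19.2 to 243 ± 32.4 (2.02 ± 0.18). Kcnip2 (2.83 ± 0.30) and Pck1 (0.65 ± 0.09) rose, and the collagen gene Col15a1 (-1.17 ± 0.15), the apelin receptor Aplnr (-0.87 ± 0.17) and Ttr (-0.83 ± 0.18) fell. Of 67 genes of oxidative phosphorylation 14 rose and 0 fell, and of 29 interferon genes 6 fell and 0 rose. Camera gave adjusted p = 9.35e-44 for oxidation, and adjusted p = 0.0221 with an estimated correlation. It gave 6.82e-13 for oxidative phosphorylation and 0.000359 for interferon genes, and adjusted p = 0.763 for both with an estimated correlation. 30 oxidation genes rose, 25 of oxidative phosphorylation rose and 8 interferon genes fell, adjusted over the list alone. The 1668 genes passing were 1012 higher and 656 lower. They were 964 to 2438 with 1 HW or HT library left out and 1024 with only HW and HT in the fit. HT2 also had lymphocyte marker genes at 262.3 CPM in sum against a median of 26.6 in the other kidneys.

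**Figure D3:**
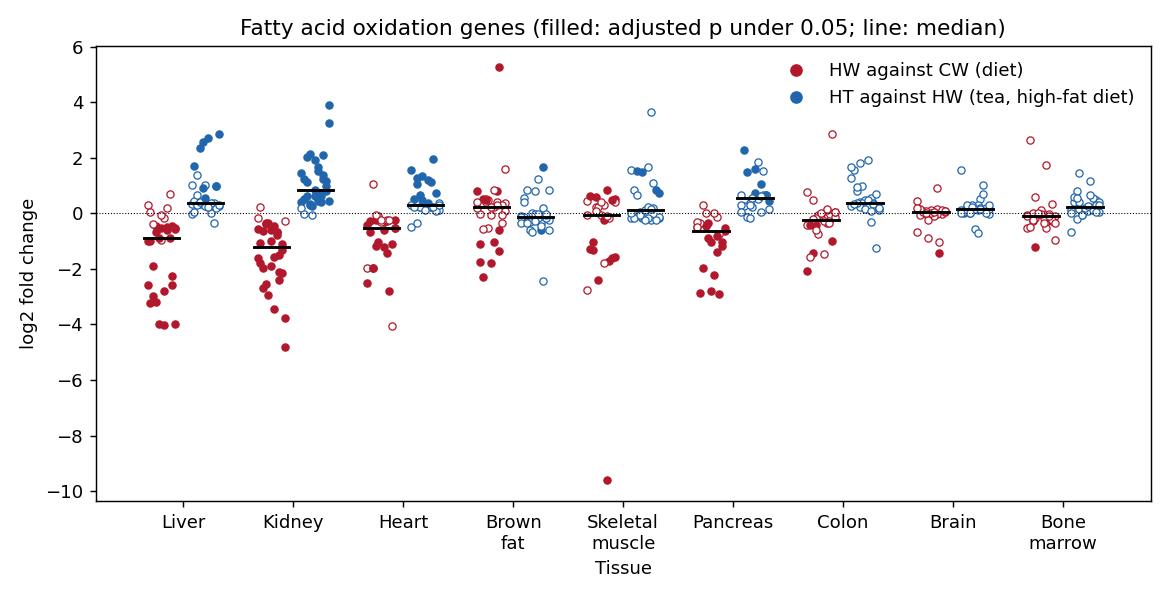
Log2 fold changes of the genes of the PPARA and fatty-acid oxidation list (points) and their medians by tissue for the diet and for tea under the high-fat diet. The median in kidney is -1.20 for the diet and 0.83 for tea.

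Under chow, tea raised Dbp in kidney from 2.71 ± 1.11 to 25 ± 9.01 CPM (3.21 ± 0.32, adjusted p = 5.22e-05) together with the clock repressors Per3 (1.36 ± 0.14) and Cry2 (1.06 ± 0.09). Hmox1 (-3.29 ± 0.50), the clock gene Nfil3 (-1.53 ± 0.22), Cyp4a12a (-1.36 ± 0.31), Pdk4 (-0.84 ± 0.15) and the chaperone Calr (-0.59 ± 0.13) fell. Of 20 clock genes 8 rose and 4 fell, or 9 and 5 adjusted over the list alone, and of 22 genes of the unfolded protein response 6 fell and 0 rose, or 11 fell adjusted over the list alone. The camera test gave adjusted p = 0.00359 and 2.27e-07, and adjusted p = 0.612 and 0.542 with an estimated correlation. The 1104 genes passing were 455 higher and 649 lower, and numbered 467 to 1217 with 1 CW or CT library left out and 1762 in DESeq2. The mitochondrial share of counts was 9.33 ± 0.38% in CW and 10.49 ± 0.67% in CT (exact permutation p = 0.0159). Tea acted differently by diet on 976 genes, 618 higher and 358 lower, led by Bmp6 (0.87 ± 0.08), Pdk4 (2.50 ± 0.21) and Acot2 (1.56 ± 0.14), each at adjusted p = 2.01e-06. This number was 494 to 1871 with 1 library left out and 1594 in DESeq2.

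The heart had the most genes differing with the diet, 6535 of 17210, 3198 higher and 3337 lower. Pdk4 fell from 5270 ± 780 to 921 ± 350 CPM (-2.52 ± 0.19, adjusted p = 1.1e-08), with Cdkn1a (-3.27 ± 0.31), Bmal1 (-3.19 ± 0.20), the lipoprotein lipase inhibitor Angptl4 (-2.79 ± 0.44) and the lipid droplet protein Plin2 (-1.41 ± 0.14). Of 28 genes of fatty-acid oxidation 18 fell and 0 rose, and of 67 of oxidative phosphorylation 54 fell and 0 rose, with Ndufa9 of complex I at -0.56 ± 0.10. The mitochondrial share of counts was 23.92 ± 1.81% in CW and 26.94 ± 2.18% in HW (exact permutation p = 0.0476). Extracellular matrix genes went up, 16 of 25 higher and 1 lower, with Lum at 1.47 ± 0.24 and Col1a2 at 0.97 ± 0.18. All 10 atrial genes rose too. Bmp10 stood at 1.33 ± 2.91 CPM in CW and 359 ± 109 in HW (8.02 ± 2.06, 7.69 to 13.75 in alternatives, adjusted p = 0.00654). Kcnj3 rose by 1.52 ± 0.20. Unequal atrium in heart samples was not told apart from diet or tea. Cilp2 rose (4.90 ± 0.89), as did the adipocyte gene Plin1 (4.95 ± 1.63, adjusted p = 0.0255), whose call ended without CW1, CW2, CW5 or HW4 (adjusted p 0.0519 to 0.0591). Lymphocyte markers also rose, 14 of 19, with 0 lower.

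Tests with camera gave adjusted p = 5.63e-09 for oxidation, 8.93e-13 for oxidative phosphorylation, 0.00157 for matrix, 0.000101 for atrial and 0.000102 for lymphocyte genes of the heart. The same lists had adjusted p = 0.55, 0.622, 0.684, 0.55 and 0.622 with an estimated correlation. 22 oxidation and 62 oxidative phosphorylation genes fell, 18 matrix genes rose and 1 fell, and 10 atrial and 16 lymphocyte genes rose, adjusted over the list alone.

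In the heart, tea under the high-fat diet raised Pdk4 to 2730 ± 402 CPM (1.57 ± 0.19, adjusted p = 2.5e-05), Plin2 (1.14 ± 0.14), the lipase Pnpla2 (0.97 ± 0.13), Timp4 (1.81 ± 0.18) and Tcf23 (1.72 ± 0.17). The Wnt antagonist Sfrp5 (-2.38 ± 0.33), the calcium channel subunit Cacna2d2 (-2.20 ± 0.52, adjusted p = 0.017) and apelin, Apln (-1.84 ± 0.23), fell. Atrial genes moved with these: 2 of 10 fell and 0 rose, also adjusted over the list alone, Kcnj3 to 73.2 ± 20.7 CPM (-0.99 ± 0.20, adjusted p = 0.00543) and Tbx5 (-0.57 ± 0.14, adjusted p = 0.0175). Bmp10 stood at 359 ± 109 CPM in HW and 52.3 ± 99.9 in HT and did not pass (adjusted p = 0.326). The atrial list had a median of -1.45 (camera adjusted p = 8.14e-05, and adjusted p = 0.55 with an estimated correlation). Of 28 genes of fatty-acid oxidation 12 rose and 0 fell, or 19 rose adjusted over the list alone (camera adjusted p = 6.48e-14), and of 17 lipid droplet genes 7 rose and 0 fell, or 7 and 1 adjusted over the list alone (8.99e-05). Both lists had adjusted p = 0.528 with an estimated correlation. With only HW and HT in the fit the calls on Cacna2d2 and Tbx5 ended (adjusted p = 0.0515 and 0.0595), and without HT3 that on Tbx5 did (0.0583). The 1083 genes passing, 636 higher and 447 lower, numbered 575 to 1599 with 1 HW or HT library left out.

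Under chow, tea changed 80 heart genes, 55 higher and 25 lower. Dbp rose from 5.28 ± 1.33 to 12.8 ± 2.79 CPM (1.27 ± 0.17, adjusted p = 0.003), with the clock repressor Nr1d1 (1.11 ± 0.18, adjusted p = 0.0115) and the desaturase Scd4 (1.11 ± 0.23, adjusted p = 0.0434). The growth factor Hbegf (-0.75 ± 0.15, adjusted p = 0.0326) and the slow myosin Myh7 (-0.65 ± 0.14, adjusted p = 0.0434) fell. The call on Nr1d1 ended without CT5 (0.0539), that on Hbegf without CW1, CW2, CW4, CT1, CT4 or CT5 (0.0537 to 0.104), and those on Scd4 and Myh7 without these or CW3 or CW5 (0.056 to 0.0939 and 0.065 to 0.147). None of the 67 genes of oxidative phosphorylation passed, with a median of -0.25 (edgeR, 0 adjusted over the list alone; camera adjusted p = 8.93e-13, and adjusted p = 0.622 with an estimated correlation). White adipocyte markers had a median of 2.13, with 0 of 15 passing and 7 higher adjusted over the list alone (camera adjusted p = 0.0114, and adjusted p = 0.622 with an estimated correlation). Without CT4 the camera adjusted p for these markers was 0.111. Atrial genes had a median of 1.33, with 0 of 10 passing, also adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.622 with an estimated correlation), and Bmp10 stood at 1.33 ± 2.91 CPM in CW and 104 ± 152 in CT (adjusted p = 0.123). The count of genes was 1 to 134 with 1 CW or CT library left out, 6 with only CT and CW in the fit, and 721 in DESeq2. CW1 and CT4 carried hepatocyte transcripts (418.2 and 202.3 CPM in sum against a median of 9.0) and CT4 lymphocyte transcripts (566.3 against 37.9), and 5 genes passed without both. The log2 fold changes were then 1.12 ± 0.21 for Nr1d1, 1.03 ± 0.26 for Scd4, -0.52 ± 0.14 for Hbegf and -0.60 ± 0.17 for Myh7 (adjusted p = 0.0596, 0.148, 0.136 and 0.176). With only CT and CW in the fit the calls on Scd4, Hbegf and Myh7 ended (0.0625, 0.0768 and 0.0556), and with no filter on low counts that on Scd4 did (0.0738). The tea effect differed by diet for 560 genes, 361 higher and 199 lower, led by Tacc2 (1.59 ± 0.20), Tcf23 (1.79 ± 0.23) and Timp4 (1.87 ± 0.24), each at adjusted p = 0.000486. That number was 234 to 1450 with 1 library left out, 237 without CW1 and CT4, and 1269 in DESeq2.

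In BAT, some thermogenic and interferon genes rose with the high-fat diet. Of 20 thermogenic genes 8 rose and 1 fell, with Prdm16, which specifies brown fat (1.02 ± 0.20, adjusted p = 0.00114), and the mitochondrial Cox7a1 (0.85 ± 0.17), and of 29 interferon genes 8 rose and 0 fell. The mitochondrial share of counts was 16.72 ± 2.32% in CW and 25.08 ± 1.41% in HW with no overlap (exact permutation p = 0.00794, the smallest possible). Of 16 heat-shock genes 6 rose and 0 fell, with the chaperonin Hspd1 at 961 ± 244 against 477 ± 81.7 CPM (1.01 ± 0.18). Of 12 glucocorticoid targets 5 fell and 0 rose, with Fkbp5 at -2.45 ± 0.49. Dbp (4.62 ± 0.27), the calcium channel gene Ryr2 (4.26 ± 0.49) and the choline transporter Slc5a7 (4.24 ± 0.82) rose, and Npas2 (-5.42 ± 0.57), Bmal1 (-4.08 ± 0.27) and the muscle ubiquitin ligases Trim63 (-4.59 ± 0.81) and Fbxo32 (-3.41 ± 0.63) fell. Muscle fibre markers had a median of -1.68, with 0 of 16 passing, also adjusted over the list alone, and CW3 held 89308.6 CPM of them against a median of 11974.6 in the other libraries.

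Camera gave adjusted p = 0.00554 for thermogenic, 0.00102 for interferon, 0.00554 for heat-shock, 0.00182 for glucocorticoid and 0.0293 for muscle fibre genes in BAT, and adjusted p = 0.906 for all 5 lists with an estimated correlation. For heat-shock genes it was 0.0661 without CW5, and for muscle fibre markers 0.0574 to 0.319 without CW1, CW3 or HW1. With adjustment over the list alone, 8 thermogenic genes rose and 2 fell, 8 interferon and 6 heat-shock genes rose, and 5 glucocorticoid targets fell. In all 4048 of 17204 genes passed, 1963 higher and 2085 lower.

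In BAT, tea under the high-fat diet lowered the uncoupling protein Ucp1 from 6760 ± 1750 to 2550 ± 1000 CPM (-1.41 ± 0.31, adjusted p = 0.0113), with Acot11 (-1.12 ± 0.24), Agpat2, of triglyceride synthesis (-1.24 ± 0.26), Apln (-2.28 ± 0.35) and Nnat (-2.11 ± 0.52, adjusted p = 0.025). Cyp2b10 (3.85 ± 0.70), the chemokine Cxcl13 (2.97 ± 0.64) and Fdft1, of sterol synthesis (2.11 ± 0.31), rose. Of 20 thermogenic genes 2 fell and 0 rose, or 5 fell adjusted over the list alone, and of 24 genes of sterol synthesis 6 fell and 1 rose, or 13 and 1 adjusted over the list alone. The camera test gave adjusted p = 0.00102 and 5.26e-05, and adjusted p = 0.906 and 0.721 with an estimated correlation. HT4 held lymphocyte transcripts at 265.6 CPM in sum against a median of 49.8. The call on Nnat ended without HW4 or HT2 (adjusted p 0.0525 to 0.0706) and with only HW and HT in the fit (0.0727). The 1039 genes passing, 555 higher and 484 lower, numbered 439 to 1667 with 1 HW or HT library left out and 541 with only HW and HT in the fit.

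Under chow, tea lowered white adipocyte markers in BAT: 4 of 15 fell and 0 rose, or 7 adjusted over the list alone, with leptin, Lep, at 21.1 ± 23.0 CPM in CW and 0.906 ± 0.660 in CT (-4.55 ± 0.90, adjusted p = 0.0178) and Nnat at 78.5 ± 40.5 and 11 ± 5.01 (-2.83 ± 0.54, adjusted p = 0.0142). Dbp (2.15 ± 0.25), the amino acid transporter Slc7a8 (1.49 ± 0.34, adjusted p = 0.0348) and the glycogen synthase Gys2 (1.40 ± 0.22) rose, and the protease Adamts9 fell (-1.59 ± 0.33, adjusted p = 0.0204). The calls ended for Lep without CT1 or CT5 (0.0573 to 0.0624), for Nnat without CT1 (0.0572), for Adamts9 without CW1, CW2, CT1, CT4 or CT5 (0.0506 to 0.0676), and for Slc7a8 without these or CW3 or CW4 (0.0529 to 0.105) and with no filter on low counts (0.0557). The markers had camera adjusted p = 0.00102, and 0.906 with an estimated correlation. Of 321 genes passing 179 were higher and 142 lower. Their number was 78 to 499 with 1 CW or CT library left out, 207 with only CT and CW in the fit, 712 in DESeq2, and 168 without CW3, HW1 and HT4, where HW1 held hepatocyte transcripts at 718.3 CPM against a median of 17.1. Slc7a8 was then at 1.49 ± 0.35 (adjusted p = 0.0592). The tea effect differed by diet for 354 genes, 146 higher and 208 lower, with Gys2 at -2.21 ± 0.31 (adjusted p = 0.0025) and Fbxl2 at -2.20 ± 0.28 (0.00241). This number was 130 to 594 with 1 library left out, 130 without the 3 above, 188 with no filter and 743 in DESeq2.

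In skeletal muscle the high-fat diet lowered genes of muscle protein breakdown. The ubiquitin ligase genes Trim63, at 3050 ± 1090 CPM in CW and 315 ± 49.8 in HW (-3.28 ± 0.25, adjusted p = 7e-08), and Fbxo32 (-2.30 ± 0.20) fell, as did 8 of the 12 genes of the atrophy list, with 1 higher. Of 12 glucocorticoid targets 9 fell and 0 rose, with Fkbp5 at -2.52 ± 0.30. Pdk4 (-2.41 ± 0.19) and the antioxidant Srxn1 (-2.12 ± 0.22) fell, and Dbp (6.60 ± 0.743 CPM in CW and 105 ± 4.95 in HW), Nnat (3.97 ± 0.72), the nicotinamide riboside kinase Nmrk2 (3.22 ± 0.30) and the muscle protease Ky (2.85 ± 0.35) rose. Transcripts of other organs fell too: 16 of 16 acinar and 11 of 11 hepatocyte markers, with Mup20, a liver protein of a family of near-identical copies, at 7.21 ± 14.9 CPM in CW and 0.0198 ± 0.0181 in HW (-8.35 ± 1.80). Acinar transcripts summed to 17042.6 CPM in CW1 and 285.2 in CW3 against a median of 1.9 in the other libraries, and hepatocyte transcripts to 416.1 in CW4 against 2.5.

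For the atrophy list in muscle camera gave adjusted p = 7.36e-08 and for glucocorticoid targets 4.35e-08, and adjusted p = 0.134 and 0.27 with an estimated correlation. Acinar and hepatocyte markers had 0.00588 and 1.65e-05, and adjusted p = 0.888 and 0.672 with an estimated correlation. The acinar value was 0.12 without CW1 and 0.963 without CW1, CW3 and CW4. 8 atrophy genes fell and 1 rose, and 10 glucocorticoid, 16 acinar and 11 hepatocyte genes fell, adjusted over the list alone. The 4120 genes passing of 16378 were 1775 higher and 2345 lower.

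Tea under the high-fat diet raised 6 of the 12 atrophy genes in muscle and lowered 0, with Fbxo32 from 396 ± 83.8 to 1170 ± 225 CPM (1.56 ± 0.20, adjusted p = 0.000385) and Trim63 from 315 ± 49.8 to 875 ± 145 (1.47 ± 0.24). Pdk4 (1.49 ± 0.18), the cationic amino acid transporter Slc7a2 (1.67 ± 0.34) and Arrdc2, a glucocorticoid target (1.63 ± 0.34, adjusted p = 0.00869), rose. Nmrk2 (-2.18 ± 0.29) and the actin-regulated transcriptional coactivator Mrtfa (-1.54 ± 0.15) fell. Of 67 genes of oxidative phosphorylation 9 fell and 0 rose. Adjusted over the list alone, 7 atrophy genes rose and 33 of oxidative phosphorylation fell (camera adjusted p = 6.61e-07 and 1.68e-11, and adjusted p = 0.134 and 0.88 with an estimated correlation). The call on Arrdc2 ended with only HW and HT in the fit (0.0544). The 1493 genes passing, 674 higher and 819 lower, numbered 685 to 1334 with 1 HW or HT library left out and 994 with no filter on low counts.

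Under chow, tea raised macrophage genes in muscle and lowered oxidative phosphorylation. Of 24 macrophage genes 11 rose and 0 fell, with the receptor Clec7a at 1.64 ± 0.32 (adjusted p = 0.00994), and the macrophage genes Fcna (2.18 ± 0.38, adjusted p = 0.00746) and Siglec1 (1.91 ± 0.32, adjusted p = 0.0066) rose. Of 67 genes of oxidative phosphorylation 31 fell and 0 rose, with Uqcrh of complex III from 260 ± 18.9 to 192 ± 16.7 CPM (-0.44 ± 0.08, adjusted p = 0.0067). The mitochondrial share of counts was 10.86 ± 2.57% in CW and 7.65 ± 0.69% in CT (exact permutation p = 0.0317). The slow-fibre light chain Myl3 (-5.19 ± 1.31, adjusted p = 0.0294) and the liver enzyme Bhmt (-6.08 ± 1.28, adjusted p = 0.0103) fell, as did 16 of 16 acinar and 9 of 11 hepatocyte markers. Each of these gene calls ended without CW1, CW3 and CW4, the libraries with acinar or hepatocyte transcripts, which leaves 2 CW libraries. The log2 fold changes were then 1.42 ± 0.44 for Clec7a, 1.99 ± 0.47 for Fcna, 1.82 ± 0.46 for Siglec1 and -0.39 ± 0.11 for Uqcrh (adjusted p = 0.248, 0.156, 0.178 and 0.189), each less than 1 SE from its value with all libraries. Those of Myl3 (-2.06 ± 1.49, adjusted p = 0.638) and Bhmt (-2.62 ± 0.73, adjusted p = 0.178) were smaller. Then 1 gene passed, against 1065 with all, 393 higher and 672 lower. The call on Myl3 also ended without CW3 or any CT library (0.0512 to 0.0755), and that on Bhmt with only CT and CW in the fit (0.113).

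In muscle under chow 14 macrophage genes rose, 60 of oxidative phosphorylation fell and 2 rose, and 16 acinar and 10 hepatocyte markers fell, adjusted over the list alone. Camera gave adjusted p = 2e-10, 3.29e-26, 0.00387 and 0.00111 in this order, and adjusted p = 0.415, 0.493, 0.888 and 0.88 with an estimated correlation. The acinar value was 0.354 without CW1, and the hepatocyte value was 0.0876 without CW1, CW3 and CW4. Genes numbered 290 to 1594 with 1 CW or CT library left out, 460 with only CT and CW in the fit, and 1641 in DESeq2. In muscle the tea effect differed by diet for 185 genes, 81 higher and 104 lower, with the ferrireductase Steap3 at -0.94 ± 0.11 and Dbp at -1.49 ± 0.19 (adjusted p = 0.000836 for both). That number was 60 to 519 with 1 library left out, 89 without CW1, CW3 and CW4, 96 with no filter and 788 in DESeq2.

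In pancreas, genes of fatty-acid oxidation fell and genes of oxidative phosphorylation rose with the high-fat diet. Of 25 genes of fatty-acid oxidation 15 fell and 0 rose, with the dehydrogenase Acadl from 54.6 ± 3.63 to 21.1 ± 7.63 CPM (-1.38 ± 0.16). Of 67 genes of oxidative phosphorylation 24 rose and 0 fell, with Ndufb10 at 0.46 ± 0.09. Dbp rose from 0.598 ± 0.235 to 32.0 ± 7.41 CPM (5.73 ± 0.45, adjusted p = 1.63e-06) and Nr1d1 by 4.06 ± 0.31, while Bmal1 (-3.80 ± 0.22), Cdkn1a (-4.34 ± 0.59) and Angptl4 (-2.79 ± 0.36) fell. Of 20 acinar genes 8 rose and 1 fell, with colipase, Clps, from 17600 ± 1680 to 26400 ± 2930 CPM (0.59 ± 0.11) and the bile salt-activated lipase Cel from 35700 ± 1390 to 51200 ± 5470 (0.52 ± 0.11). Adjusted over the list alone, 18 oxidation genes fell and 1 rose, 34 of oxidative phosphorylation rose and 1 fell, and 9 acinar genes rose and 2 fell. The camera test gave adjusted p = 7.11e-12, 8.72e-12 and 0.00866, and adjusted p = 0.255, 0.255 and 0.846 with an estimated correlation. The acinar value was 0.0553 without HW1. The 1722 genes passing of 13470 were 845 higher and 877 lower, and 1110 without CW2.

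In pancreas, tea under the high-fat diet raised Acadl from 21.1 ± 7.63 to 43.9 ± 3.50 CPM (1.06 ± 0.16, adjusted p = 0.00224), with Cep85 (2.15 ± 0.33) and the uncoupling protein Ucp2 (1.52 ± 0.18), and lowered the sulfotransferase Sult1c2 (-1.65 ± 0.21). The trypsinogens Try4 (0.84 ± 0.14) and Try5 (0.84 ± 0.15), near-identical copies, rose. Of 25 genes of fatty-acid oxidation 8 rose and 0 fell, and of 67 of oxidative phosphorylation 7 fell and 0 rose. Lymphocyte markers rose, 7 of 13, with 0 lower and the immunoglobulin Ighd at 5.09 ± 1.13 (adjusted p = 0.0206), and HT1 held 349.3 CPM of them against a median of 18.5. 14 oxidation and 11 lymphocyte genes rose and 26 of oxidative phosphorylation fell, adjusted over the list alone. Tests with camera gave adjusted p = 1.68e-11 for oxidation, 8.5e-16 for oxidative phosphorylation and 0.0016 for lymphocyte genes, and adjusted p = 0.255, 0.255 and 0.777 with an estimated correlation. The lymphocyte value was 0.196 without HT1, and the call on Ighd ended without HT1, HW1, HW2, HW3 or HW5 (0.0502 to 0.0919) and without HT1 and CT7 (3.92 ± 1.14, adjusted p = 0.0899). The 507 genes passing, 252 higher and 255 lower, numbered 188 to 756 with 1 HW or HT library left out and 284 without HT1 and CT7.

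Under chow, tea changed 54 pancreas genes, 19 higher and 35 lower. Nr1d1 rose from 2.15 ± 0.809 to 10.3 ± 4.05 CPM (2.26 ± 0.30, adjusted p = 0.0109) and Tef by 1.55 ± 0.24 (0.0109). Try4 (0.68 ± 0.15, adjusted p = 0.0395) and Try5 (0.73 ± 0.16, adjusted p = 0.0395) were the 2 of 27 digestive enzyme genes that passed. The methionine adenosyltransferase Mat2a (-0.75 ± 0.13, adjusted p = 0.0109), Rgmb (-1.04 ± 0.20, adjusted p = 0.0283) and the stress sensor Ern1 (-0.89 ± 0.18, adjusted p = 0.0404) fell. Calls ended for Tef without CW2 (0.0516), for Mat2a without CW4 (0.0537), for Try4 without CW2, CW3, CW4, CW5, CT1, CT2 or CT4 (0.0685 to 0.145), for Try5 without CW2, CW3, CW5, CT1, CT2, CT4 or CT7 (0.0583 to 0.158), for Rgmb without any library but CT5 (0.0519 to 0.0905), for Ern1 without any but CW5 (0.0522 to 0.137), and for Nr1d1 with only CT and CW in the fit (0.0609). With no filter on low counts the calls on Try4, Try5, Rgmb and Ern1 ended (0.13, 0.134, 0.0644 and 0.0797). Adjusted over the list alone, 4 digestive enzyme genes rose (camera adjusted p = 2.5e-07, and adjusted p = 0.382 with an estimated correlation). The 67 genes of oxidative phosphorylation had a median of 0.17 with 0 passing, also adjusted over the list alone (camera adjusted p = 5.23e-14, and adjusted p = 0.255 with an estimated correlation). The count was 5 to 75 with 1 CW or CT library left out, 127 without HT1 and CT7, 18 with only CT and CW in the fit, and 199 in DESeq2. In pancreas the tea effect differed by diet for 241 genes, 100 higher and 141 lower, led by ferritin Ftl1 (-1.02 ± 0.14), the galactokinase Galk1 (-1.18 ± 0.16) and Sult1c2 (-2.37 ± 0.33), each at adjusted p = 0.000654. This number was 92 to 395 with 1 library left out and 577 in DESeq2.

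In colon the genes that differed with the diet were led by the clock. Dbp rose from 4.11 ± 3.69 to 94.5 ± 15.7 CPM (4.52 ± 0.59, adjusted p = 0.000795) and Ciart by 3.60 ± 0.44, and Bmal1 (-2.27 ± 0.33) and Npas2 (-2.22 ± 0.25) fell; of 20 clock genes 11 rose and 4 fell. Pdk4 (-2.07 ± 0.38, adjusted p = 0.0183) and Acot1 (-1.42 ± 0.19) were among 5 of 28 genes of fatty-acid oxidation that fell, with 0 higher. Sc5d (0.47 ± 0.07) was the 1 of 24 genes of sterol synthesis that rose, and 0 fell. 14 clock genes rose and 4 fell, 11 oxidation genes fell and 1 rose, and 18 sterol genes rose, adjusted over the list alone. Camera gave adjusted p = 2.42e-10, 3.07e-08 and 2.06e-16, and adjusted p = 0.14, 0.75 and 0.61 with an estimated correlation. The call on Pdk4 ended without CW2, HW2 or HW4 (0.0519 to 0.0676). Of 19416 genes 54 were higher and 36 lower, 90 in all, with 48 to 99 when 1 CW or HW library was left out and 59 with only HW and CW in the fit. DESeq2 called 294, and 484 passed with the first 2 principal components as covariates.

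Tea under the high-fat diet changed 1 colon gene, Cwh43, of lipid remodelling of membrane anchors, which rose from 16.7 ± 1.35 to 32.2 ± 3.57 CPM (0.95 ± 0.11, adjusted p = 0.00125). At unadjusted p below 0.05 edgeR had 1610 genes, and DESeq2 called 30 after adjustment. With principal components 93 passed, and 23 for tea under chow. The count was 2 without HW4 and 2 without HT2. With adjustment over the list alone, 17 of 28 genes of fatty-acid oxidation rose, with a median of 0.38, and 9 of 15 white adipocyte markers rose, with a median of 0.90, while 0 of either list passed over all genes (camera adjusted p = 1.41e-18 and 1.43e-08, and adjusted p = 0.578 and 0.61 with an estimated correlation). Under chow 0 genes passed in edgeR, with 1773 at unadjusted p below 0.05 and 77 called by DESeq2. Without CW5 19 genes passed, and without CW2 or CT5 1. Of 22 genes of the unfolded protein response 0 passed over all genes, and 11 were lower adjusted over the list alone (camera adjusted p = 3.07e-08, and adjusted p = 0.61 with an estimated correlation). The tea effect differed by diet for 0 genes in edgeR, with 992 at unadjusted p below 0.05 and 9 called by DESeq2, and for 1 without HW2.

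In brain 14 of 19481 genes differed with the diet, 5 higher and 9 lower. Plin4, a lipid droplet protein, fell from 52.2 ± 12.3 to 5.02 ± 1.84 CPM (-3.38 ± 0.42, adjusted p = 0.00112), with Sult1a1 (-1.60 ± 0.16), Angptl4 (-1.42 ± 0.18), Cdkn1a (-2.16 ± 0.38, adjusted p = 0.0367) and the protease Htra1 (-0.82 ± 0.15, adjusted p = 0.0367). Dbp (1.42 ± 0.26, adjusted p = 0.0367), the sulfurtransferase Tst (0.85 ± 0.14, adjusted p = 0.0238) and the tubulin Tubb2b (0.80 ± 0.11) rose. Of 12 glucocorticoid targets 1 fell and 0 rose, or 7 fell adjusted over the list alone (camera adjusted p = 1.41e-07, and adjusted p = 0.269 with an estimated correlation). Acinar transcripts summed to 6194.1 CPM in HW5 against a median of 6.2 in the other brains: 0 of 6 markers passed, 6 rose adjusted over the list alone, and camera gave adjusted p = 0.00428, adjusted p = 0.545 with an estimated correlation, and 0.242 without HW5. Calls ended for Dbp without CW2, CW3 or any HW library (0.0758 to 0.128), for Tst without CW1, CW2, HW1, HW3 or HW4 (0.0504 to 0.102) and for Cdkn1a and Htra1 without any library but CW5 (0.0504 to 0.128 for both). With only HW and CW in the fit 5 genes passed, and Dbp, Tst, Tubb2b, Cdkn1a and Htra1 had adjusted p = 0.11, 0.0972, 0.0972, 0.137 and 0.0984. With no filter on low counts the call on Cdkn1a ended (0.0516). The count was 4 to 26 with 1 CW or HW library left out, 97 in DESeq2 and 54 with the first 2 principal components as covariates. With these components 16 genes passed for tea under the high-fat diet, 1 for tea under chow and 2 for the interaction.

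Under the high-fat diet tea raised 2 brain genes, Plin4 to 45.5 ± 34.7 CPM (3.18 ± 0.42, adjusted p = 0.00731) and Sult1a1 from 6.91 ± 1.51 to 13.7 ± 0.831 (0.99 ± 0.15, adjusted p = 0.0298), and lowered 0, with 1269 genes at unadjusted p below 0.05 in edgeR and 18 called by DESeq2. The call on Sult1a1 ended without HW1 to HW4 or HT1 to HT4 (0.0539 to 0.123), and with only HW and HT in the fit 0 genes passed (0.229 for Plin4 and Sult1a1). The count was 1 without HT1, HT2, HT3 or HT4 and 6 without HT5. With adjustment over the list alone, 6 of 16 heat-shock genes were lower and 7 of 12 glucocorticoid targets higher, with 0 of either passing over all genes (camera adjusted p = 3.58e-07 and 2.13e-05, and adjusted p = 0.302 and 0.369 with an estimated correlation). Under chow 0 genes passed in edgeR, with 1244 at unadjusted p below 0.05 and 13 called by DESeq2, and 1 passed without CT1. In that comparison the 12 striatal genes had a median of 1.31 and the 11 cerebellar genes a median of -1.44, with 0 passing, also adjusted over the list alone (camera adjusted p = 3.81e-08 and 0.00162, and adjusted p = 0.451 and 0.573 with an estimated correlation). The tea effect differed by diet for 0 genes in edgeR, with 946 at unadjusted p below 0.05 and 5 called by DESeq2.

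In bone marrow Asns, asparagine synthetase, fell with the diet from 156 ± 24.1 CPM (n = 3) to 58.8 ± 3.74 (n = 5; -1.40 ± 0.11, adjusted p = 2.1e-05), with the transcription factor Atf5 (-1.62 ± 0.24), Trib3 (-3.38 ± 0.73, adjusted p = 0.0403), Igfbp3 (-2.43 ± 0.26), Cr2, a complement receptor of B cells (-1.09 ± 0.16) and metallothionein Mt1 (-0.77 ± 0.10). Angptl2 (1.38 ± 0.24, adjusted p = 0.0102), Ace (1.30 ± 0.24, adjusted p = 0.0174), the interferon-induced Mx1 (1.11 ± 0.19, adjusted p = 0.0108), Acaca, of fatty-acid synthesis (0.68 ± 0.12, adjusted p = 0.00994), and Dbp (0.96 ± 0.20, adjusted p = 0.0255) rose. Of 29 interferon genes 4 rose and 0 fell, of 29 cell-cycle genes 6 fell and 0 rose, and of 22 genes of the unfolded protein response 4 fell and 0 rose. Lymphocyte markers moved with these, 5 of 18 lower and 0 higher, as did erythroid markers, 2 of 12 lower and 0 higher, and HW3 held acinar transcripts at 285.5 CPM against a median of 30.7. Without HW3 1782 genes passed, against 455 with it, 156 higher and 299 lower of 18479.

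Adjusted over the list alone, in marrow 15 interferon genes rose, 14 cell-cycle genes fell and 1 rose, and 4 genes of the unfolded protein response, 7 lymphocyte and 4 erythroid markers fell. The camera test gave adjusted p = 6.33e-09, 9.95e-06, 0.0333, 5.12e-05 and 6.08e-05, and adjusted p = 0.595, 0.726, 0.83, 0.624 and 0.726 with an estimated correlation. The value for the unfolded protein response lay between 0.0722 and 0.227 without CW2, CW4, HW1 or HW4. Calls ended without CW1 for Angptl2 (0.119), Mx1 (0.113), Acaca (0.103) and Ace (also without CW2, 0.0609 to 0.137), for Trib3 without CW1, CW2, HW1, HW2, HW4 or HW5 (0.0757 to 0.239) and with no filter on low counts (0.0604), and for Dbp without CW1, HW1, HW2, HW4 or HW5 (0.0509 to 0.217). The count was 30 to 1782 with 1 CW or HW library left out and 1394 in DESeq2.

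Tea under the high-fat diet changed 0 marrow genes in edgeR, with 2084 at unadjusted p below 0.05 and 71 called by DESeq2, and 4, 1 and 1 passed without HW1, HT2 and HT4. Of 16 heat-shock genes 0 passed over all genes and 14 were lower adjusted over the list alone, with a median of -0.54 (camera adjusted p = 8.79e-14, and adjusted p = 0.44 with an estimated correlation). Under chow, with 3 CW and 2 CT libraries, edgeR called 0 genes, with 2988 at unadjusted p below 0.05 and 484 called by DESeq2. With only these arms in the fit 178 genes passed, without HW3 34, and without CW1 1. The tea effect differed by diet for 0 genes in edgeR, with 1806 at unadjusted p below 0.05 and 44 called by DESeq2, for 1 without CW1, CT4 or HW1 or with no filter and for 2 without HT3.

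Across tissues, genes that differed with the diet often moved the opposite way with tea under the high-fat diet. Of 24376 calls for the diet and 6868 for tea, 4458 were of one gene in one tissue in opposite directions and 38 in the same direction. Independent lists of these sizes would share 843 in opposite and 846 in the same direction. Both comparisons use the HW libraries. Groups simulated with no effect gave a mean of 0.1 opposite calls in 10 simulations, which leaves open how much the shared libraries add where effects are real. With the HW libraries split in 20 ways, so that each comparison had its own, the tissue medians summed to 1388 opposite and 14.5 same calls, where those of independent lists summed to 169. The opposite calls over these splits ranged from 34 to 321 in BAT, 90 to 530 in heart, 77 to 360 in kidney, 222 to 433 in liver, 15 to 123 in pancreas and 44 to 388 in skeletal muscle. By tissue the opposite and same calls were 966 and 3 in heart, 966 and 1 in skeletal muscle, 817 and 6 in liver, 762 and 5 in BAT, 643 and 20 in kidney, 301 and 3 in pancreas, 2 and 0 in brain, 1 and 0 in colon, and 0 and 0 in bone marrow. The covariance of the log2 fold changes across genes was -0.1905 in liver, where simulated groups gave -0.0417, and -0.2228 in heart, where they gave -0.0443. In brain it was -0.0731 against -0.0763, in colon -0.0468 against -0.0507 and in bone marrow -0.0445 against -0.0402. In the same libraries the mean log2 CPM of 4 heat-shock genes (Hspa1a, Hspa1b, Dnajb1 and Hsph1, chosen after the values were seen) was lower in HT than in HW in 9 of 9 tissues, by 0.76 to 2.43, and higher in HW than in CW in 8, by up to 2.04. None of 27 exact permutation tests by tissue passed (lowest adjusted p = 0.214), and again a lone one cannot. With each replicate number averaged over its tissues, the exact p was 0.0556 for HT against HW and 0.143 for HW against CW.

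The effects of tea under the 2 diets, which share no libraries, were not correlated beyond other groupings of the same libraries. Across genes, which are not independent replicates, Pearson's r was 0.036 in brain (exact two-sided permutation p = 0.877), 0.091 in BAT (0.617), -0.198 in heart (0.206), 0.034 in kidney (0.771), 0.165 in liver (0.102), 0.117 in pancreas (0.285), 0.226 in colon (0.245), 0.102 in skeletal muscle (0.379) and 0.111 in bone marrow (0.140). With no filter on low counts the liver value was 0.124 (exact permutation p = 0.0474). None of these 9 values would pass after adjustment over the tissues.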

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

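The tests of the clock ratio, of independent variation of the heat-shock genes and of RNA of other organs were chosen after the result was seen. In 37 of 462 groups (8.0%) the highest or lowest library lay far from the rest of its group, by the ratio of its gap to the range, where chance gives about 1 in 20. For genes of liver these were, in CPM with the median of the others, Cfd in CW5 (1.31; 0.0809), Cyp4a10 in CW1 (8120; 6240), Isg15 in HW2 (23.1; 11.7), Clec2h in HW1 (8.42; 19.0) and Cyp4a31 in HT4 (163; 120). In kidney they were Cyp4a14 in CW3 (1510; 2510), Ttr in HW1 (115; 165) and Acot2 in HT3 (76.2; 61.2). In heart they were Bmp10 in CW3 (6.53; 0), Angptl4 in CW5 (121; 80.8), Plin2 in CW1 (247; 162), Scd4 in CT1 (134; 76.5), Pdk4 in HT1 (2040; 2910), and in HW1 Cilp2 (12.1; 28.8), Kcnj3 (88.6; 157) and Pnpla2 (561; 424). In skeletal muscle they were Mup20 (33.8; 0.523) and Bhmt (26.5; 0.388) in CW4 and Steap3 in CT4 (28.8; 25.2). In pancreas they were Cel in CW5 (37700; 34900), Try5 in CW4 (28300; 20100), and in HW1 Angptl4 (4.80; 1.82), Acadl (34.5; 18.2) and Ucp2 (20.1; 11.8), and in colon Dbp in CW2 (10.6; 2.41).

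Total counts stood out in brain CW3 (82.9 M; 62.2 M), heart CT4 (53.9 M; 63.65 M) and HT1 (83.1 M; 66.55 M), pancreas HT4 (50.2 M; 42.1 M), skeletal muscle CT5 (136.1 M; 69.75 M) and bone marrow HW1 (64.4 M; 78.95 M). Percentages of mitochondrial counts stood out in brain CW4 (10.14; 5.21) and CT5 (8.74; 5.70), heart CW1 (20.78; 24.84), pancreas CT7 (1.07; 0.44) and HT2 (0.65; 0.52) and colon HT1 (8.01; 4.88).

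The effect of tea differed between the diets, by edgeR's interaction test, for 63 of the 101 gene and tissue pairs tested. These pairs were chosen for a tea effect or for leading the interaction itself, so their share says nothing of other genes. The differences in log2 fold change (HT against HW, less CT against CW) in liver were Cntnap1 4.28, Slc16a5 2.83, Cyp4a14 3.11, Gbp10 -2.19, Clec2h -3.31, Cyp4a31 2.28, Cpt1a 0.71, Cyp4a10 2.57, Cyp8b1 1.94, Asl 1.67, Ass1 1.17, Fbp1 0.85, Dbp -3.28, Per3 -2.86 and Pdk4 2.85 (adjusted p 1.82e-05 to 0.0364). In kidney they were Cyp4a14 3.59, Kcnip2 2.66, Cyp4a10 2.07, Acot1 2.35, Col15a1 -1.08, Dbp -3.17, Per3 -1.45, Cry2 -0.88, Hmox1 4.14, Nfil3 2.05, Pdk4 2.50, Bmp6 0.87 and Acot2 1.56 (2.01e-06 to 0.00962). In heart they were Timp4 1.87, Tcf23 1.79, Pdk4 1.69, Sfrp5 -3.40, Cacna2d2 -3.20, Apln -1.50, Plin2 1.13, Pnpla2 1.10, Dbp -1.70, Nr1d1 -1.38, Hbegf 1.05, Myh7 1.44, Kcnj3 -1.26, Tbx5 -0.78 and Tacc2 1.59 (0.000486 to 0.0376). In BAT they were Apln -1.95, Ucp1 -2.08, Acot11 -1.31, Agpat2 -1.65, Fdft1 1.83, Dbp -1.95, Gys2 -2.21 and Fbxl2 -2.20 (0.00241 to 0.0453), and in skeletal muscle Pdk4 1.55, Mrtfa -1.59, Steap3 -0.94 and Dbp -1.49 (0.000836 to 0.00794). In pancreas they were Ucp2 1.38, Sult1c2 -2.37, Acadl 1.19, Nr1d1 -2.79, Tef -1.77, Rgmb 1.64, Ftl1 -1.02 and Galk1 -1.18 (0.000654 to 0.0122).

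The number of genes was set against other splits of the same libraries, 100 per comparison and 56 for the diet in marrow. It is given here as the real number and the highest of the other splits. With so few splits, and no adjustment over the comparisons, they do not exclude chance. For the diet 1 split, the real one, gave as many in BAT (4048; 147), heart (6535; 333), kidney (3342; 296), liver (4050; 164), pancreas (1722; 656) and skeletal muscle (4120; 806). In brain (14; 83), colon (90; 1029) and marrow (455; 790) 2 splits did, the other with more genes than the arms. For tea under the high-fat diet the real split alone gave as many in kidney (1668; 774), liver (1075; 348), pancreas (507; 145) and skeletal muscle (1493; 30). In brain (2; 17) and heart (1083; 1101) 2 splits did, and in BAT (1039; 1293) 3 did. For tea under chow it can be excluded in BAT (321; 8), heart (80; 2), kidney (1104; 40), liver (420; 3), pancreas (54; 32) and skeletal muscle (1065; 645). For the interaction the real split alone did so in BAT (354; 248), heart (560; 102), kidney (976; 7), liver (442; 42) and pancreas (241; 29), and 2 splits did in skeletal muscle (185; 197). Chance also stays open for tea under the high-fat diet in colon (1; 177), where 8 splits gave as many. For tea under the high-fat diet in marrow (0; 576), tea under chow in brain (0; 1447) and colon (0; 436) and the interaction in brain (0; 89) and colon (0; 80), the splits decide nothing, since all 100 reach a number of 0. For the diet in brain and colon a split called several times the real number, which points to a structure of the samples other than the arms.

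Clock genes differed between the arms across tissues. The scaling between libraries is argued against by the log2 ratio of Dbp to Bmal1, which no scaling moves and which was 1 or more higher in HW than in CW with no overlap in 8 tissues. A few libraries that stand apart are argued against by the same 8 tissues without them. Collection at another hour in each arm cannot be told apart from an effect of diet, or of tea under chow, since the ratio was lower than in CW in 0 tissues in HW and in 0 in CT, and the labels give no hour. A shift of feeding time or of the clock itself by diet or tea stays open as untested.

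Heat-shock genes (Hspa1a, Hspa1b, Dnajb1 and Hsph1) varied together across the tissues of a replicate number: HW1 lay below the mean of its arm in 9 of 9 tissues, by a mean log2 of -2.04, and CT2 above it in 9 of 9, by 1.24. Independent variation of single libraries is argued against by permuting numbers within tissue and arm (one-sided p = 1e-05, the smallest that 100000 permutations can give). A processing batch that follows the number in all arms is argued against because the numbers did not shift alike over the arms (one-sided permutation p = 0.762). The arms also differed, lower in HT than in HW in 9 of 9 tissues and higher in HW than in CW in 8, with 0 of 27 tests passing adjustment, and why was not tested. A candidate explanation is that a number within an arm marks 1 animal in each tissue; a batch or day within an arm stays open, and no biological cause of the animals' difference was tested.

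Abundant transcripts of another organ appeared in single libraries. RNA of that organ in the library is a candidate explanation that fits 7 libraries, where more than 25 of the 50 most abundant donor transcripts that the tissue lacks were over 5 times the other libraries. These were SkeletalMuscle CW1 (50 of pancreas, implied share 2.22%), CW3 (27, 0.053%) and CW4 (48 of liver, 0.308%), brain HW5 (37 of pancreas, 0.89%), BAT HW1 (50 of liver, 0.457%), and heart CW1 (46 of liver, 0.245%) and CT4 (48, 0.167%). It stays open in marrow HW3 (12 of pancreas, 0.026%) and in BAT CW3, which held 89308.6 CPM of muscle fibre markers against a median of 11974.6 and where the test decides nothing, since the muscle transcripts that BAT lacks are scarce in muscle too (Hoxc10, the most abundant, at 65 CPM). Whether this RNA entered at dissection, extraction or sequencing was not tested.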

How the results depend on the processing

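The fits chosen after seeing the data are named above. The 37 counts of genes stayed within 1.5 times under RLE scaling and with counts divided by 2, and 33 did so with no filter. The cause of each move below was not tested. Of the 212 genes, 0 lost their call under RLE scaling, 10 with no filter, 0 of 210 in DESeq2, 0 of 210 with counts divided by 2, 15 without the libraries that stand apart, 17 of 196 with only the arms of the contrast and 0 of 18 with principal components, and leaving out a library ended 159 of 2209 calls. None reversed. Of 82 list results, 79 passed no longer with an estimated correlation, and 5 without the libraries that stand apart. There 2 marker lists changed direction: muscle fibre in BAT under the diet (camera adjusted p = 0.84) and acinar in skeletal muscle for tea under chow (0.0886). Leaving out a library ended 14 of 801 list calls. In simulated data 18 to 38% of changes of 1.5-fold were recovered, and depth, the spread between animals and the number of libraries were not told apart as limits there.

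DESeq2 gave in the order diet, tea under the high-fat diet, tea under chow and interaction, where more than 1.5 times away: brain 97, 18, 13 and 5; colon 294, 30, 77 and 9; bone marrow 1394, 71, 484 and 44. For tea under chow and the interaction it gave 712 and 743 in BAT, 721 and 1269 in heart, 1762 and 1594 in kidney, 779 and 740 in liver, 199 and 577 in pancreas and 1641 and 788 in skeletal muscle. With no filter, the interaction gave 188 in BAT, 96 in skeletal muscle and 1 in bone marrow, tea under the high-fat diet 994 in skeletal muscle, and the correlation of tea effects in liver became 0.124. Without libraries apart, brain diet gave 7, marrow diet 1782, and tea under the high-fat diet 1095 in kidney and 284 in pancreas. Tea under chow gave 168 in BAT, 5 in heart, 860 in liver, 127 in pancreas, 1 in skeletal muscle and 34 in marrow, and the interaction 130 in BAT, 237 in heart, 801 in liver and 89 in skeletal muscle. With principal components brain gave 54, 16, 1 and 2 in the order above, and colon 484, 93 and 23. With only the arms of the contrast, the diet gave 5 in brain and 59 in colon, tea under the high-fat diet 0 in brain, 541 in BAT, 1024 in kidney and 585 in liver, and tea under chow 207 in BAT, 6 in heart, 760 in liver, 18 in pancreas, 460 in skeletal muscle and 178 in marrow. With HW split, median opposite calls summed to 1388.

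The replicate numbers do not pair the samples: median correlations of same-numbered deviations were -0.058 to 0.053 across tissues. With the number as a block, 20 of 212 genes and 0 of 82 lists passed no longer (adjusted p 0.0513 to 0.135). These were Nr1d1, Scd4, Hbegf, Myh7 (tea under chow) and Cacna2d2 (tea under the high-fat diet) in heart, Slc7a8, Lep, Adamts9 and, for both tea comparisons, Nnat in BAT, Try4, Try5 and Ern1 in pancreas, Dbp, Tst, Cdkn1a, Htra1 and Sult1a1 in brain, Cfd in liver and Myl3 in skeletal muscle. The block gave 6 for brain diet and 1383 for marrow diet, 1, 584 and 19 for tea under the high-fat diet in brain, BAT and marrow, 110, 1, 712, 33 and 685 for tea under chow in BAT, heart, liver, pancreas and skeletal muscle, and 112, 320, 716, 115 and 3 for the interaction in BAT, heart, liver, skeletal muscle and marrow.

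Only libraries of the arms compared were left out singly for the ranges below, which do not hold the values without HT6 in liver and HW3 in marrow for tea under chow (860 and 34, above). For the diet, leaving out each library of HW and CW in turn gave brain 4 to 26, BAT 3093 to 4194, heart 5364 to 6363, kidney 2596 to 3218, liver 3442 to 3832, pancreas 1110 to 1518, colon 48 to 99, skeletal muscle 3395 to 4276 and marrow 30 to 1782. For tea under the high-fat diet, HT or HW libraries gave brain 1 to 6, BAT 439 to 1667, heart 575 to 1599, kidney 964 to 2438, liver 754 to 1454, pancreas 188 to 756, colon 1 to 2, skeletal muscle 685 to 1334 and marrow 0 to 4. For tea under chow, CT or CW libraries gave brain 0 to 1, BAT 78 to 499, heart 1 to 134, kidney 467 to 1217, liver 188 to 466, pancreas 5 to 75, colon 0 to 19, skeletal muscle 290 to 1594 and marrow 0 to 1. For the interaction, libraries of the 4 arms gave brain 0 to 0, BAT 130 to 594, heart 234 to 1450, kidney 494 to 1871, liver 295 to 801, pancreas 92 to 395, colon 0 to 1, skeletal muscle 60 to 519 and marrow 0 to 2. In marrow, leaving out a CT library leaves 1, which is assumed to vary like the other groups.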

Other observations

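The gene lists of this part were chosen after their values were seen. Of 12 glucocorticoid targets in the heart, 9 fell under the high-fat diet and 0 rose, with a median log2 fold change of -1.36 (camera adjusted p = 8.14e-05, and adjusted p = 0.55 with an estimated correlation), and 9 fell adjusted over the list alone. Tea under the high-fat diet raised 2 of them and lowered 0, or 6 adjusted over the list alone, with a median of 0.85 (camera adjusted p = 0.000133, and adjusted p = 0.599 with an estimated correlation). Genes of detoxification moved likewise in heart, where 12 of 24 fell and 1 rose with the diet (median -0.38, 0.00015, and adjusted p = 0.528 with an estimated correlation; 12 and 1 adjusted over the list alone). Tea raised 3 and lowered 1, or 7 and 1 adjusted over the list alone (median 0.27, 0.000298, and adjusted p = 0.528 with an estimated correlation). In kidney 14 of 29 fell and 1 rose with the diet (median -0.22, 5.09e-05, and adjusted p = 0.127 with an estimated correlation; 14 and 1 adjusted over the list alone). Tea raised 6 and lowered 0, or 9 adjusted over the list alone (median 0.17, 0.00241, and adjusted p = 0.44 with an estimated correlation).

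In liver, 4 of 18 acute-phase genes rose with tea under the high-fat diet and 0 fell, or 12 adjusted over the list alone, with a median of 0.84 and a mean of 1.76 (camera adjusted p = 5.07e-05, and adjusted p = 0.63 with an estimated correlation).

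White adipocyte transcripts, mostly Car3, summed to 2263.2 to 3381.4 CPM in the 5 HW livers against a median of 283.0 in the other livers.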
